A study of Drosophila melanogaster with 2 samples.

How the data were processed

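Ovaries of Drosophila melanogaster females aged 3 to 10 days were dissected, and total RNA was isolated, depleted of ribosomal RNA (rRNA) with Ribo-Zero and made into strand-specific libraries with the NEBNext Ultra Directional kit, per the labels' protocols. There was 1 library from flies carrying 1 mutant copy of cutoff (cuff) over the balancer chromosome CyO, made from ovaries of both mutant alleles mixed, and 1 library from flies carrying a different mutant allele of cuff on each chromosome. They are called the heterozygote library and the mutant library.

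The values are raw read counts, which the authors made before they were deposited by pooling identical reads, mapping each distinct sequence and giving its count, per the file headers. Beside the count stand chromosome, start, stop and annotation. Every sequence was 45 nt long, none was repeated within a library, and the counts were whole numbers that had not been normalised. The submitters' processing notes name CASAVA 1.7 and the genome build dm3. The aligner, the mismatches allowed, the treatment of reads that match several places and the source of the annotation names are not given in the sources used here. Each sequence carried 1 position and 1 annotation. The 284075 sequences found in both libraries had the same position and annotation in each, so a read that matches several copies of a repeat was always placed at the same copy, and reads with 1 genomic place could not be told from reads with several.

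Annotations were sorted into genes (CG, CR or FBgn identifiers), rRNA, small structural RNAs (tRNA, snRNA, snoRNA, scaRNA, 7SL, RNase P), transposons (repeat names of the LTR, LINE, DNA and RC types), the mitochondrial genome, sequences named by a database accession, reads without annotation, and the remainder. Of 10563 CG and CR identifiers, 10224 were matched to a gene symbol in a RefSeq gene table, by locus tag or by a synonym that only 1 gene had. Coordinates are those of the authors' files, in dm3. The only annotation to hand was of the build BDGP6, from which names, gene types and gene strands were used and no coordinates, so exons, introns and UTRs were not told apart. A gene was given the chromosome that held most of its reads. The span given for it is that of its reads.

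Each library was scaled to its total over genes without rRNA and small structural RNAs, 7056947 reads in the heterozygote library and 624888 in the mutant library. RPM means reads for each 1000000 reads of that total. Leaving the structural RNAs out of the total was decided after the data were seen, because 5S rRNA and snoRNAs carry gene identifiers. The log2 ratio is that of the mutant over the heterozygote library, with a pseudocount of 0.5 reads added in each. Intervals are exact Poisson 95% intervals of a count, exact (Clopper-Pearson) binomial 95% intervals of a share, and the 95% interval of a ratio conditional on the sum of both counts. They cover counting error only, since reads without molecular identifiers are not independent molecules. One read was worth 0.142 RPM in the heterozygote library and 1.6 RPM in the mutant library. The limit that a count of 0 allows was set at 3 reads, 0.425 and 4.8 RPM.

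With 1 library per genotype no test between genotypes was possible, and no p-value or standard error is given. Numbers of genes past a 2-fold and a 4-fold ratio describe these libraries only. Genes entered these numbers with at least 50 reads over both libraries after the deeper one was scaled to the shallower, and transposon families had the same minimum. Gene lists were written before the data were examined, as were the bounds of 5 piRNA clusters, the classes of transposon families and the scaling to a total over genes, apart from the structural RNAs left out of it. The cluster bounds and the classes of families came from memory. Of 18 lists, 15 had at least 3 members past the minimum. The median log2 ratio of each of these was placed among 10000 random lists of the same size, matched by deciles of mean expression. For 2 list names a synonym pointed to an unrelated gene, and they were left out. Of 64 transposon families in the lists, 54 were matched to a repeat name in the files.

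Genes were named by a rule fixed with the lists. It takes cuff, the 4 members of each list with the largest absolute log2 ratio past the minimum, and the 10 genes with the highest and the 10 with the lowest log2 ratio. Any gene outside the rule is said to have been chosen after its values were seen.

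The libraries keep the strand of each read. Of the gene reads on the 5 large chromosome arms, 86.3% in the heterozygote library and 89.3% in the mutant library lay opposite to the gene, the orientation of a first read from a kit that marks the second strand. Sense reads alone had been planned for the gene values. The files do not give gene strands, so genes were counted on both strands, and sense reads by the BDGP6 strand became an alternative. Overlapping and antisense genes are therefore not separated by strand. Clusters were counted on each genomic strand. No sense and antisense share was computed for transposon families, because the orientation of the copies was not among the sources used here.

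Alternatives planned beforehand were median-of-ratios, TMM and ribosomal protein scaling, a minimum of 1 and of 200 reads, a thinned heterozygote library, a pseudocount of 5, identical sequences counted once, the inner 80% of each cluster, gene-annotated reads masked, and transposon reads outside the clusters. Weighting by the number of genomic places and a comparison of exons with whole gene bodies were planned but not run, because the files tell neither. Added after the data were seen were a total that includes structural RNAs, sense reads alone, unannotated cluster reads alone, and a weighting of heterozygote reads by GC content. Those weights were fitted within genes of the large arms, so that each gene has its own ratio and all genes share 1 curve over the GC count of a read, from 0.389 at 10 to 1.37 at 33 of 45 bases.

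Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and TMM edgeR 4.0.16 in R 4.3.3. The ratios were tested on simulated counts of these libraries. Among 4507 simulated genes, those made 2-fold and 4-fold higher had median log2 ratios of 1.00 and 1.97, and the interval held the true ratio in 97.8% and 97.9% of them. Those lowered by the same factors had median log2 ratios of -0.94 and -1.85, with the true ratio held in 94.9% and 93.8%. Among 4529 genes simulated with counting error alone, 1 was past a 2-fold ratio upward and 0 downward, with an SD of 0.2 in the log2 ratio.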

Results

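Cutoff (cuff) is a nuclear protein of the Drosophila germline that acts with Rhino at dual-strand piRNA clusters, the loci that give rise to piRNA precursors from both genomic strands. Total RNA of ovaries was sequenced to compare transcripts of flies with 1 mutant copy of cuff and of flies with a mutant allele on both chromosomes. Each genotype had 1 library, so no difference below has a replicate check, and every interval covers counting error only. The heterozygote library held 12174309 reads of 45 nt and the mutant library 18207434.

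Ribosomal RNA took 16.4% of the heterozygote library (95% binomial interval 16.4% to 16.4%) and 95% of the mutant library (95% to 95%), although both had been depleted of it. Gene-annotated reads were 58.0% and 3.43% of all reads, or 7056947 and 624888 reads, so the mutant library was 11.3 times shallower over genes. Among reads other than rRNA, genes took similar shares, 69.4% in the heterozygote library and 69.1% in the mutant library. Transposon reads took 0.774% and 5.54% of them, mitochondrial reads 8.28% and 2.11%, and small structural RNAs 14.4% and 19.2%. The mean GC content of gene reads was 50.3% in the heterozygote and 53% in the mutant library. Thinned to the depth of the mutant library, the heterozygote library gave 461471 distinct gene sequences, against 478805 in the mutant library.

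**Figure D1:**
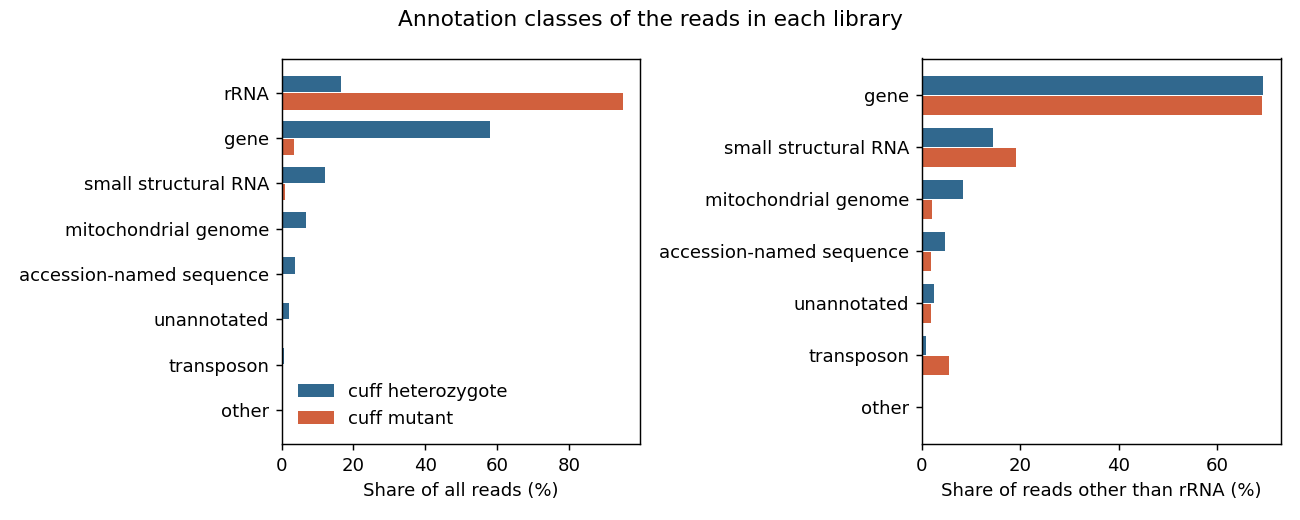
Share of reads by annotation class, in percent of all reads (left) and of reads other than rRNA (right), with 1 bar per library. Ribosomal RNA filled 95% of the mutant library, and transposon reads made up 5.54% of its remainder against 0.774% in the heterozygote library.

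The mutated gene itself was lower in the mutant library. Reads of cuff (CG13190) lay on chromosome 2R between positions 7773590 and 7775028 of dm3. There were 96 in the heterozygote library, 13.6 RPM (11 to 16.6), and 2 in the mutant library, 3.2 RPM (0.388 to 11.6). The log2 ratio was -1.77, with a counting interval from -5.15 to -0.20. cuff was below the read minimum set for the other genes, and the labels do not say whether its alleles remove the transcript.

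Transposon transcripts were higher in the mutant library. Summed over 136 elements, they were 11161 RPM in the heterozygote and 80216 RPM in the mutant library, 7.19-fold higher. Of 65 elements past the read minimum, 37 were at least 2-fold higher, 26 of these at least 4-fold, and 1 was at least 2-fold lower. The classes fixed beforehand differed. The median log2 ratio was 3.58 over 4 telomeric elements, 2.04 over 27 families known mainly from the germline and 0.65 over 9 families known mainly from the somatic follicle cells. With reads weighted by GC content these medians were 3.72, 2.63 and 1.28. With identical sequences counted once they were 2.83, 1.69 and -0.08, and 29 elements were at least 2-fold higher and 3 at least 2-fold lower. That setting scales each library to its distinct gene sequences, 2945978 and 478805, which alone moves every log2 ratio by -0.88.

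All 4 telomeric retrotransposons measured, which maintain chromosome ends in flies, were higher. HeT-A had 64.5 RPM in the heterozygote and 2754 RPM in the mutant library, a log2 ratio of 5.42 (5.27 to 5.57). TAHRE had a log2 ratio of 4.78 (4.45 to 5.12), TART-B of 2.39 (2.14 to 2.64) and TART-A of 1.98 (1.81 to 2.14). With identical sequences counted once these were 4.60 for HeT-A, 3.98, 1.67 and 1.32. Among germline families, 19 of 27 were at least 2-fold higher and 0 at least 2-fold lower. With identical sequences counted once 16 were higher and 1, invader6, was lower, and higher ones numbered 16 with TMM and 22 with GC weighting. BEL was 56.5-fold higher (133 and 7531 RPM), the Max-element 44.1-fold (97.6 and 4310 RPM), invader3 34.6-fold, HMS-Beagle 29.4-fold, diver 28.2-fold, gypsy12 22.2-fold and Burdock 14.1-fold. Their log2 ratios, in the same order 5.82, 5.46, 5.11, 4.88, 4.82, 4.47 and 3.81, were 4.20, 4.15, 4.02, 3.47, 3.48, 2.95 and 2.93 with identical sequences counted once. The copia family gave the most transposon reads, 3101 RPM in the heterozygote and 25677 RPM in the mutant library, 8.28-fold higher, a log2 ratio of 3.05, or 2.23 with identical sequences counted once. The long interspersed elements jockey, with a log2 ratio of 2.78, Doc, with 1.31, and the F-element, with 1.26, were also higher. Counted once, they had 2.14, 1.52 and 0.59. The roo family, the most abundant of those that stayed below 2-fold, had a log2 ratio of 0.63 (0.54 to 0.72), or 0.09 counted once. For invader6 it was -0.34 (-1.03 to 0.23), with 0.03 under GC weighting and -1.02 counted once.

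Of the 9 somatic families, 2 were at least 2-fold higher, gypsy10 with a log2 ratio of 1.66 (1.14 to 2.13) and gypsy6 with 1.39 (1.07 to 1.69). With identical sequences counted once these were 0.89 and 0.60, and 0 of the 9 were 2-fold higher, whereas with GC weighting 5 were, among them Idefix at 1.28. The gypsy, ZAM and Idefix elements are controlled by the flamenco cluster in follicle cells. Of these, gypsy had a log2 ratio of 0.51 (0.22 to 0.78) and Idefix of 0.65 (0.28 to 0.99), and ZAM was below the read minimum. With identical sequences counted once gypsy and Idefix had -0.18 and -0.08, of which the scale of that setting alone accounts for a move of -0.88. The mdg1 family had a log2 ratio of -0.62 (-0.95 to -0.32), which was 0.15 when reads were weighted by GC content. R1 and R2, which insert into rRNA genes, had log2 ratios of 3.72 (3.67 to 3.78) and 2.58 (2.47 to 2.68), in the library whose rRNA share was also higher, and 2.59 and 1.93 with identical sequences counted once. The element at least 2-fold lower was BS, at -1.52 (-2.11 to -1.03), and it was -0.57 after GC weighting. Each family sum takes in all copies, as the authors assigned the reads.

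**Figure D2:**
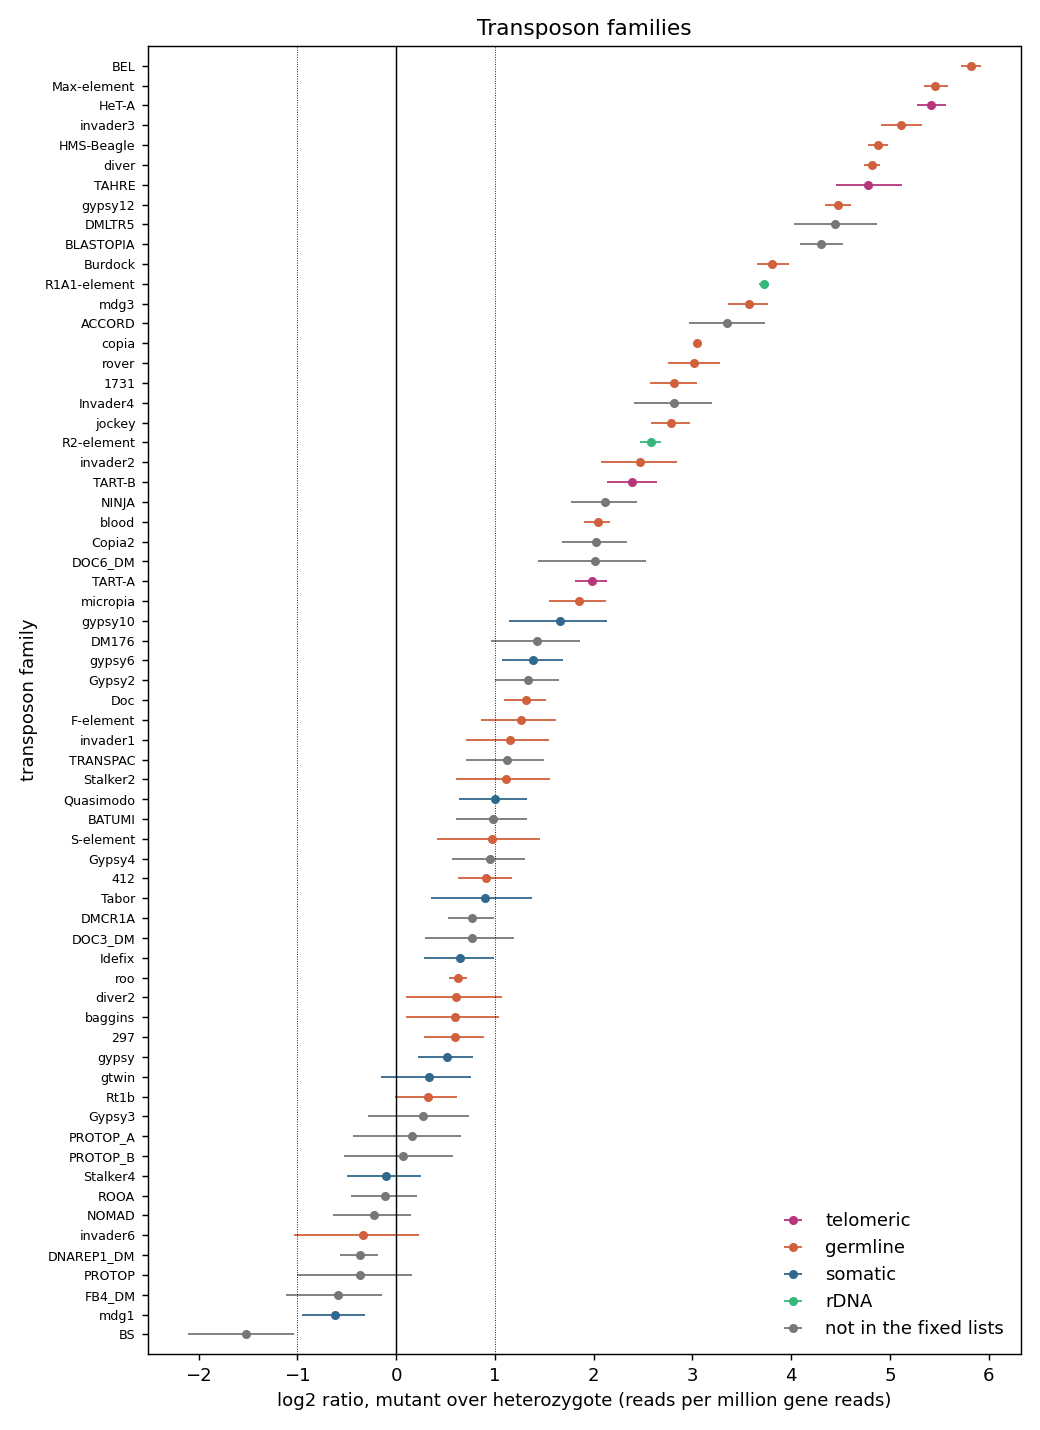
Log2 ratio of the mutant over the heterozygote library for the 65 transposon elements past the read minimum, coloured by class, with 95% counting intervals as bars and dotted lines at 2-fold. BEL, at 5.82, was the highest and BS, at -1.52, the lowest, and all 4 telomeric elements were at 1.98 or higher.

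Reads placed in the dual-strand piRNA clusters differed in direction. The positions given for each cluster are those of its first and last read, not the bounds fixed beforehand. In cluster 42AB, on 2R from 2144677 to 2381898, reads were 215 RPM in the heterozygote and 939 RPM in the mutant library, a log2 ratio of 2.13 (1.99 to 2.27). In 38C, on 2L from 20148736 to 20224720, the log2 ratio was 1.92 (1.68 to 2.15). In 80EF, on 3L from 23273992 to 23314058, it was -2.06 (-2.77 to -1.49). The uni-strand cluster 20A, on X from 21392183 to 21431753, had a log2 ratio of -0.70 (-1.03 to -0.41), and flamenco, on X from 21505761 to 21682867, one of 0.70 (0.30 to 1.07). With identical sequences counted once, 42AB had 0.98, 38C 0.57 and flamenco 0.03, where the scale alone moved each by -0.88. In the inner 80% of the clusters, 20A had -0.26 and flamenco 1.09.

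The annotation of the reads separated these values. Reads of 42AB that carry a transposon name were 181 RPM in the heterozygote and 930 RPM in the mutant library. Of the 581 in the mutant library, 262 were of gypsy12, 167 of invader3 and 81 of mdg3. Some other families placed there were lower, such as ROOA, with 68 and 1 reads (log2 ratio -2.02). Reads of 42AB without annotation went the other way, 33.7 RPM (29.6 to 38.3) in the heterozygote library and 9.6 RPM (3.52 to 20.9) in the mutant library, from 238 and 6 reads, a log2 ratio of -1.70 (-3.27 to -0.67). In 38C, 588 of 608 reads in the heterozygote library and 202 of 203 in the mutant library had transposon names, mostly copia and gtwin. Unannotated 38C reads numbered 12 and 0, too few for a difference to be detectable at this depth. In 80EF, 971 of 1061 heterozygote reads were annotated to genes, and transposon reads numbered 90 and 2. Unannotated reads had a log2 ratio of -0.86 (-1.37 to -0.42) in 20A and of 0.18 (-0.77 to 0.93) in flamenco. Over the whole genome it was -0.36 (-0.38 to -0.33). A read that matches several copies of a repeat cannot be traced to the cluster itself.

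Reads placed in 42AB lay on both strands in each library. The plus strand held 46.1% of 1515 reads (binomial interval 43.6% to 48.7%) in the heterozygote and 42.8% of 587 reads (38.7% to 46.9%) in the mutant library. Of these mutant reads, 581 had transposon names and cannot be traced to the cluster. The 6 without annotation were too few for a strand share (50%, 11.8% to 88.2%). Transcription of 42AB from both strands was therefore not measured in the mutant library. In the uni-strand clusters the plus strand held 10.8% (9.34% to 12.3%) in 20A and 13.0% (10.1% to 16.4%) in flamenco in the heterozygote library, and 5.32% (1.75% to 12%) and 13.6% (6.43% to 24.3%) in the mutant library. In 38C it held 16.4% (13.6% to 19.6%) in the heterozygote and 5.42% (2.74% to 9.49%) in the mutant library, where 202 of 203 reads had transposon names. In 80EF it held 74.6% (71.8% to 77.1%) of 1061 heterozygote reads and 95.5% (77.2% to 99.9%) of 22 mutant reads. Among genes, 13.7% of heterozygote and 10.7% of mutant reads lay on the strand opposite to the usual one.

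**Figure D3:**
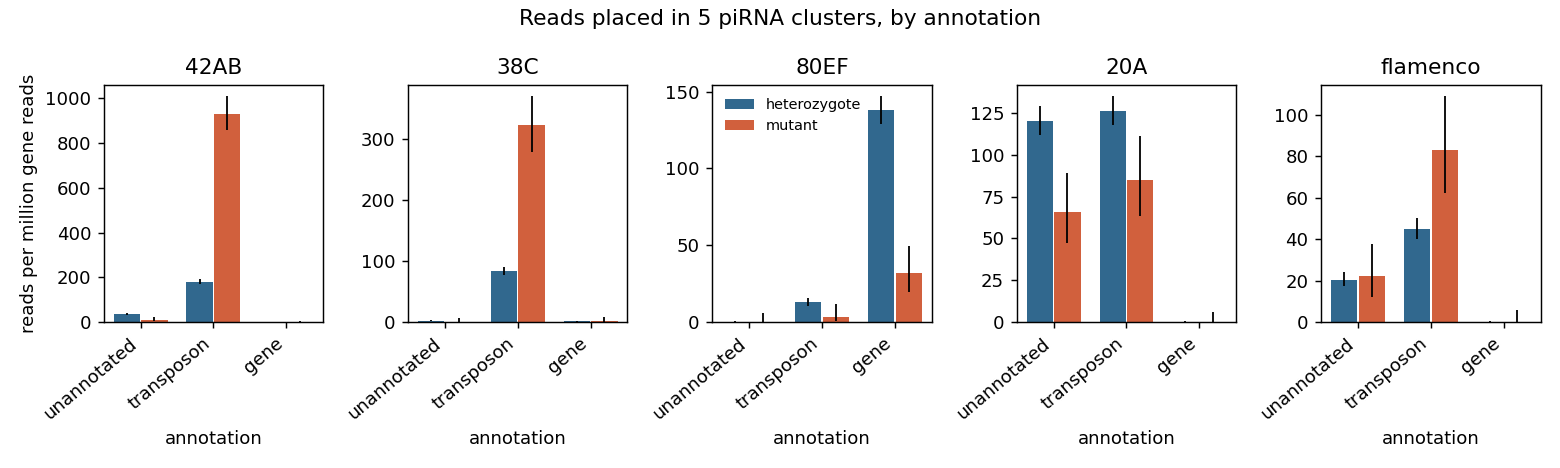
RPM of reads placed in 5 piRNA clusters, by annotation and library, with exact Poisson 95% intervals as bars and a separate vertical scale per cluster. In 42AB the transposon-named reads were at 930 RPM in the mutant library and 181 RPM in the heterozygote library, and the unannotated reads at 9.6 and 33.7 RPM.

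Genes of muscle had the highest median among the 15 lists measured at the minimum of 50 reads. With a minimum of 1 read, the antimicrobial list (4.24) and the list of fat body, gut or haemocytes (3.79) had higher medians than muscle (3.50), but most antimicrobial members and several of the others had 3 reads or fewer, so that order was not measured. Of 15 muscle genes past the minimum, 13 were at least 2-fold higher in the mutant library and none was 2-fold lower, and the list median of 3.67 lay at percentile 100 of random lists. Troponin T, encoded by upheld (up, CG7107), was 42.7-fold higher (5.38 and 232 RPM), troponin C at 73F (TpnC73F) 41.2-fold higher (2.13 and 89.6 RPM), paramyosin (Prm) had a log2 ratio of 4.49 (3.86 to 5.16) and troponin I (wupA) of 4.36 (3.90 to 4.85). All 15 also had reads in the heterozygote library.

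Heat shock genes divided. Of 14, 8 were at least 2-fold higher and none was 2-fold lower, with a median of 2.27 (percentile 100), in the library whose muscle genes were also higher. With a minimum of 200 reads, 8 of them were measured, and their median of 0.34 lay inside the random range. The small chaperone gene Hsp27 was 22.3-fold higher (37.7 and 842 RPM), starvin (stv), a co-chaperone gene, had a log2 ratio of 4.18 (3.56 to 4.83), and Hsp70Ba and Hsp70Ab had 3.63 and 3.57. The Hsp70 genes are near-identical copies whose reads cannot be assigned to 1 of them with certainty. The constitutive chaperone genes Hsp83, at -0.38, and Hsc70-4, at -0.05, were chosen after their values were seen.

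The measured genes of follicle cells, of yolk proteins and of fat body, gut or haemocytes were higher in the mutant library, beside the muscle genes. The eggshell lists, given below, did not lie above the random range. Of 6 follicle cell genes past the minimum, from 26 listed, 4 were at least 2-fold higher, with a median of 1.90 (percentile 99.9). The adhesion gene Fas3 had a log2 ratio of 3.04 (2.79 to 3.29), the matrix metalloproteinase gene Mmp2 2.61, emc 2.13 and zfh1 1.68. All 3 yolk protein genes were higher, Yp3 with 1.97 (1.83 to 2.11), Yp2 with 1.5 and Yp1 with 1.02 (median at percentile 99.7). Of 5 genes of fat body, gut or haemocytes past the minimum, from 27 listed, 3 were at least 2-fold higher, with a median of 2.10 (percentile 99.9). Papilin (Ppn) had 3.79, the collagen gene Col4a1 2.24, the lipid carrier gene apolpp 2.10 and the fatty acid synthase gene FASN1 0.96.

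Eggshell genes went both ways. Of 9 vitelline membrane genes, 4 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -0.92 (percentile 0.10). The lower ones included fs(1)N, at -1.83 (-2.09 to -1.60), and closca (clos), at -1.80, and the higher ones Vm26Aa, at 2.53, and Vm34Ca, at 1.44. With a minimum of 1 read the median was 0.18. Every listed gene named Vm was above 0, also those below the minimum, such as Vm32E at 1.53 (0.86 to 2.12) and Vm26Ac at 1.13. Also below the minimum, CG4009, Femcoat, Fcp3C and CG13084 were below 0. The median therefore does not describe the list as a whole. Of 5 chorion genes, 1 was at least 2-fold higher, Cp19 at 1.93 (1.64 to 2.20), and the others were Pxd at 0.59, Cp18 at 0.52, Cp16 at -0.57 and Cp15, chosen after its values were seen, at -0.11 (median 0.52, percentile 88.3). Measured with a minimum of 1 read, 18 chorion genes had a median of -0.43, below the random range (percentile 0.29).

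Genes of the cytoplasmic piRNA machinery were lower as a list. Of 22, 16 had a log2 ratio below 0, 3 were at least 2-fold lower and 1 was 2-fold higher, with a median of -0.42 (percentile 0.61). AGO3 (CG40300), a piRNA-binding Argonaute whose reads lay on 3L from 23547703 to 23642474, was 6.51-fold lower (505 and 76.8 RPM), at -2.70 (-3.16 to -2.31). The Tudor-domain genes papi and tej had -1.24 and -1.21, and vasa (vas), a germline RNA helicase, had 1.13 (0.88 to 1.36). AGO3 reads held 35% GC and its log2 ratio after GC weighting was -2.13. With GC weighting the list median was -0.36 and with a minimum of 200 reads -0.09, both inside the random range. With GC weighting 1 list in place of 3 lay below the central 95% of random lists. Genes of the nuclear piRNA machinery had a median of 0.10 (percentile 63.0). Of 20, 2 were at least 2-fold higher and none was 2-fold lower. The histone methyltransferase gene eggless (egg) had 1.38 (1.01 to 1.73), thoc5 1.26, sbr 0.94 and Bootlegger (Boot) -0.65.

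Germline genes were spread around 0, with 5 of 28 at least 2-fold higher, 7 at least 2-fold lower and a median of -0.06 (percentile 50.7). The thioredoxin gene deadhead (dhd) was 10158 RPM in the heterozygote and 3298 RPM in the mutant library, at -1.62 (-1.69 to -1.56), and bag of marbles (bam) had -1.62 (-2.48 to -0.96). Ovarian tumor (otu) and hu li tai shao (hts), both needed for oogenesis, had 1.36 and 1.35. Of 17 DNA damage genes, 13 were below 0, 2 were at least 2-fold lower and 1 was higher, with a median of -0.43 (percentile 1.20). The recombination gene spn-B had -1.56 (-2.36 to -0.93), the checkpoint kinase gene mei-41 -1.09 and PolZ1 -0.87, and the transcription factor gene Xrp1 2.66 (2.37 to 2.95). The DNA damage median was -0.20 with a minimum of 1 read, -0.59 with one of 200 reads, -0.34 with sense reads alone and -0.36 with GC weighting, in each case inside the random range.

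Of the other lists, 4 had at least 3 members past the minimum and lay inside the random range. Chromatin silencing genes had a median of 0.21 (percentile 82.5), with 2 of 20 at least 2-fold higher, Su(z)12 at 2.30 (1.82 to 2.74) and egg. Su(var)3-7 had 0.86 and Ino80 0.60. Genes of termination, decapping and splicing, processes in which Cutoff has been studied, had a median of -0.08 (percentile 28.0). Of 19, 1 was at least 2-fold higher, the exonuclease gene pacman (pcm) at 1.37 (0.99 to 1.72), followed by su(f) at 0.99, Rat1 at 0.96 and Patr-1 at 0.87. The 3 genes beside piRNA clusters had a median of 1.12 (percentile 93.8), with DIP1, next to flamenco, at 1.42 (0.97 to 1.82), Pld, next to 42AB, at 1.12 (0.74 to 1.47) and spir, next to 38C, at 0.45. The 82 ribosomal protein genes had a median of -0.05 (percentile 84.8). Of these, 14 were at least 2-fold higher and 6 lower, and RpL23A, RpL4, RpS10b and RpL28 had 3.72, 3.68, 3.14 and 2.31. Testis, oviduct and antimicrobial lists had 1 member each past the minimum and were not placed in a random range, Pif1A at 3.52, Hr39 at -0.06 and Rel at -0.01.

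**Figure D4:**
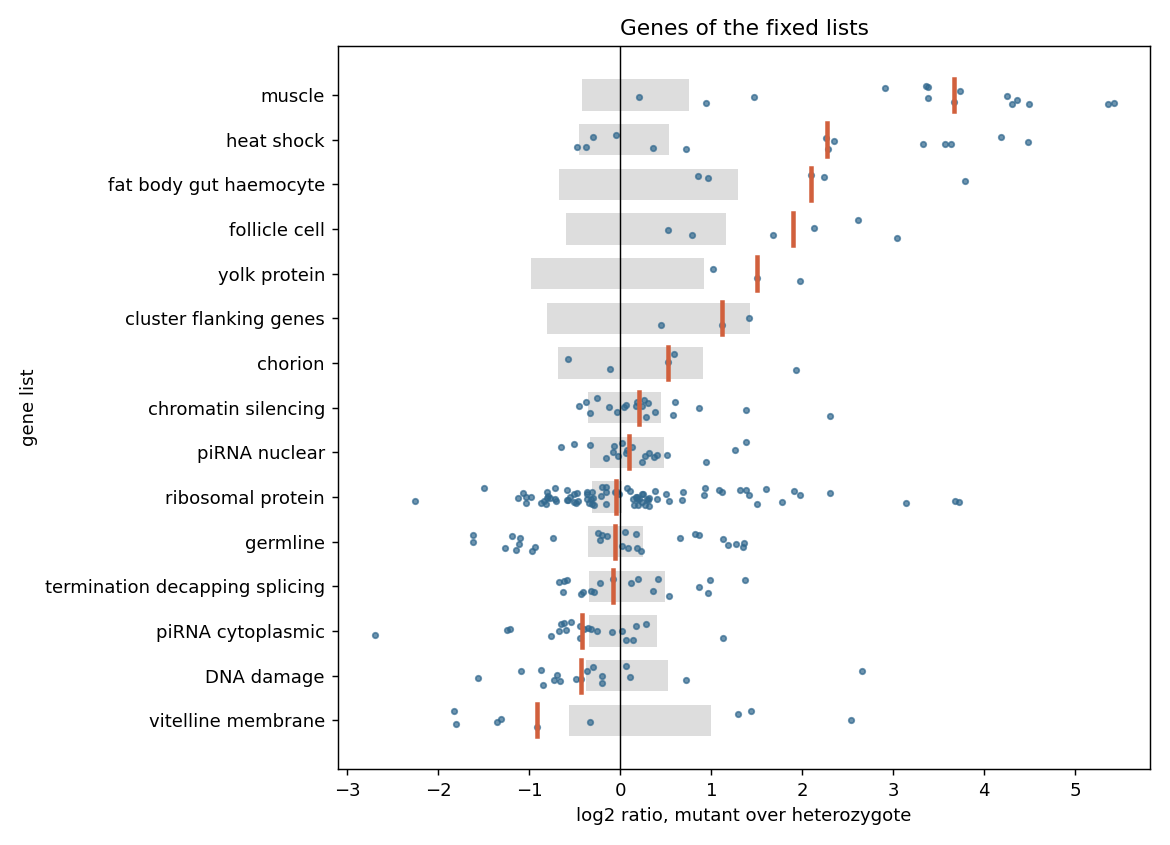
Log2 ratios of the genes in each list past the read minimum (blue points), the list median (orange line) and the central 95% of medians of 10000 matched random lists (grey). The muscle median of 3.67 lay above a random range that ended at 0.75. The vitelline membrane median of -0.92 lay below one that began at -0.56, although 3 of its 9 genes were at least 2-fold higher.

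Over all 4839 genes past the minimum, 762 were at least 2-fold higher and 339 at least 2-fold lower in the mutant library, and 230 and 21 passed 4-fold. These are numbers by size, not calls. The 10 highest were CG31760, at 6.40 (5.51 to 7.58), CG15721, at 5.55, up, TpnC73F, CG18628 (5.31), mfas (5.15), the peptidase gene Ance (5.08), the transcription factor gene salm (4.84), the phosphodiesterase gene Pde8 (4.77) and NUCB1 (4.69). CG31760 reads lay on 2L from 12148742 to 12170096 and numbered 10 and 78.

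The lowest was the carboxylesterase gene alpha-Est1 (CG1031), on 3R from 3371430 to 3374832, with 1260 and 4 reads and a log2 ratio of -4.63 (-6.68 to -3.44). It was followed by CG33941 on chromosome 4 (-3.70), c(2)M, a gene of the synaptonemal complex (-2.89), CG12129 (-2.88), AGO3, Stlk (-2.64), CG17883 (-2.52), CG2201 (-2.42), CG14464 (-2.35) and Ork1 (-2.29). Reads of CG33941, Stlk, CG17883 and CG14464 held 32.0%, 34.2%, 37.7% and 34% GC and those of c(2)M 39.2%. After GC weighting, CG33941 had -2.90, Stlk -1.97, CG17883 -2.05, CG14464 -1.71 and c(2)M -2.47.

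The balance of higher and lower genes depended on the scale. Higher genes were 69.2% of those past 2-fold with the total over genes, but 44.8% with TMM (574 and 706 genes) 48.2% with median-of-ratios scaling (599 and 643) and 45.5% with structural RNAs in the total (581 and 695), which moved every log2 ratio by -0.28, -0.24 and -0.27. Under these scales the medians of the nuclear piRNA list (-0.18, -0.14 and -0.17) and the chromatin list (-0.07, -0.02 and -0.06) were below 0. Under ribosomal protein scaling the medians of the germline list (0.02) and the ribosomal protein list (0.03) were above 0.

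**Figure D5:**
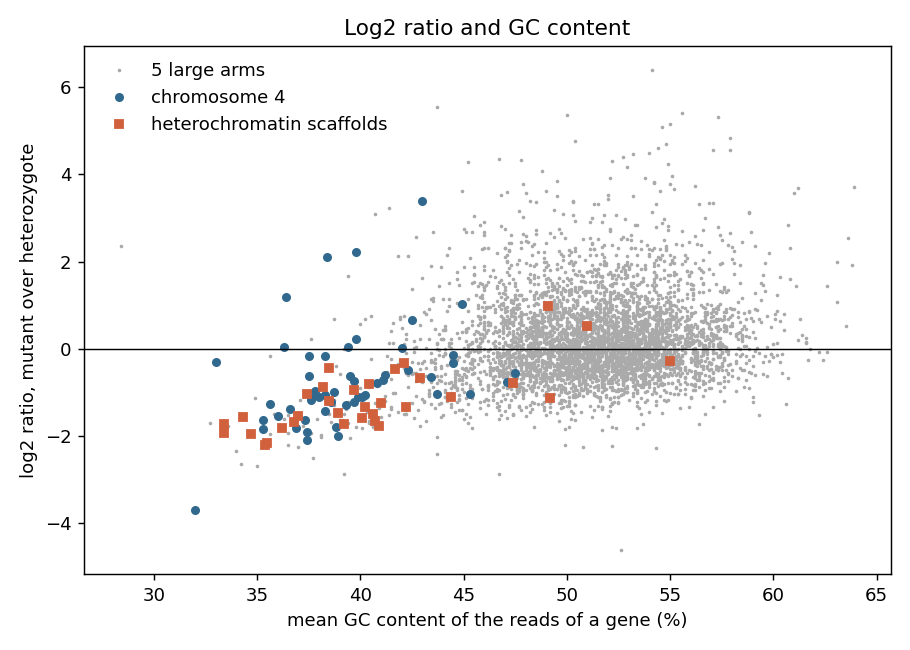
Log2 ratio of each gene past the read minimum against the mean GC content of its reads in percent, with genes of chromosome 4 in blue and of heterochromatin scaffolds in orange. The 52 genes of chromosome 4 had a median of -0.99 and the 33 genes on heterochromatin scaffolds one of -1.35.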

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

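Annotations outside the comparisons above are given where they had at least 50 reads over both libraries and more than 3 of them in the mutant library. They also had to be higher in the mutant than in the heterozygote library beyond counting error. Here the 50 reads were counted without scaling, unlike the read minimum for genes. Sequences of other annotation classes were not searched in this way. Chosen only after the results had been seen were, for the muscle genes, the tests of GC content, germline share and muscle share, and, for chromosome 4 and heterochromatin, the comparison with genes of matched GC content.

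Reads named Dm_hsr-n numbered 1441 and 520, a log2 ratio of 2.03 (1.88 to 2.17), and reads named Dm_hsr-c 468 and 79, a log2 ratio of 0.94 (0.57 to 1.28). Reads named si2 had a log2 ratio of 1.46 (1.27 to 1.63), those named si1 one of 0.87 (0.65 to 1.08) and those named si5 one of 0.80 (0.31 to 1.23), whereas those named si3 and si4 were lower, at -0.89 (-1.49 to -0.40) and -1.15 (-1.61 to -0.75). CR40659, with 24 and 26 reads and so below the scaled minimum, had a log2 ratio of 3.61 (2.76 to 4.48). Others with such numbers of reads were lower, among them CR41437, at -1.90 (-2.73 to -1.25), CR41111, at -1.69 (-2.18 to -1.27), and CR42206, at -1.54 (-2.44 to -0.85). What these names stand for is not given in the sources used here, and their difference between genotypes has no replicate check.

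The muscle genes had a median log2 ratio of 3.67, and all 15 had reads in the heterozygote library too. Weighting by GC content left the list median at 3.56, above a random range that ended at 0.75, which argues against GC bias as the whole cause. Thinning the heterozygote library left it at 3.53, but thinning does not change the expected ratio, so this cannot decide on low counts. A lower share of germline cells alone would raise all other cells alike, if none of the listed genes were expressed in the germline. The muscle median exceeded the follicle cell median by 1.77 (bootstrap interval over members 0.75 to 3.15). This leaves a lower germline share open, because germline reads of a listed gene would hold its ratio down and could not be told apart. A larger share of muscle tissue in the mutant sample stays open as a hypothesis that no value here decides, because the 86.7% of members at least 2-fold higher are the pattern itself. The abundant muscle genes Msp300 (112 and 1152 RPM) and Mhc (26.4 and 349 RPM) were chosen after their values were seen, and an effect of the genotype was not tested.

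Genes on heterochromatin scaffolds and chromosome 4 had a median log2 ratio of -1.07 over 85 genes, against 0.06 on the large arms, and their median GC content was 39.3% against 51.4%. Compared with genes of the large arms within 1 percentage point of GC they were not lower, with a median difference of 0.15 (bootstrap interval 0.01 to 0.24). This cannot decide on their location, because the arms were not divided by distance from the centromere. AT-rich genes counted with the arms, such as AGO3 on 3L and Stlk on 2R, were themselves among the 10 lowest. The trend of GC within genes was too weak to account for the gap, because after weighting by it these genes were still lower, at -0.73 (-0.89 to -0.53). GC bias of the library, the location of these genes and another property that they share with AT-rich genes of the arms cannot be told apart here. The matched difference lay slightly above 0 and the weighted one below it.

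In cluster 42AB, transposon-named reads were higher while unannotated reads were lower in the mutant library. If the former were reads of copies elsewhere, placed in the cluster by the authors, they would follow each family's ratio outside the clusters, which predicts 1231 reads. The 581 observed were 0.472 of this (Poisson interval 0.435 to 0.512), an interval that holds the bound of 0.5 set beforehand and so leaves this open. The unannotated reads stayed lower after GC weighting, at -1.24 (-2.81 to -0.20), a value that rests on 6 mutant reads. This cannot decide on GC bias. The same weighting also left genes of chromosome 4 and heterochromatin lower, for which GC bias stays open. A lower output of the cluster in the mutant remains open, on the unannotated reads and on families such as ROOA. ROOA had 68 and 1 reads in 42AB and a log2 ratio of 0.37 outside the clusters. LOOPER1 had 40 and 0 reads in 42AB but also 20 and 0 outside the clusters, so its loss cannot be tied to 42AB. Other families were higher there, among them invader3 (log2 ratio 6.16), mdg3 (3.73), gypsy12 (3.44) and the Max-element (2.73).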

How the results depend on the processing

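Depth limits the precision of the mutant values, since 1 read was worth 1.6 RPM. The total with structural RNAs, GC weighting, sense reads and unannotated reads were chosen after the data were seen. No paired analysis was possible because each genotype had 1 library and the groups shared only 1 replicate number. Exon values and place weighting were not run. The log2 ratio of cuff ranged from -2.06 to -0.35 and was below 0 under every alternative run. Of the other values for genes, lists and elements, 1074 stayed inside their counting interval, spread or range, 305 left it and 1, the median of the vitelline membrane list that lay below the random range, turned to 0.18 with a minimum of 1 read. Of 1380 log2 ratios of genes, lists and elements under alternatives, 48 had another sign, 28 of them of elements, 13 of lists and 7 of genes.

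Genes at least 2-fold lower numbered 643 with median-of-ratios scaling, 706 with TMM and 695 with structural RNAs in the total, and those 4-fold lower 55, 61 and 60, since these scales lower every ratio. In the same order, 42AB had log2 ratios of 1.89, 1.85 and 1.86, and 38C of 1.68, 1.63 and 1.64. With a minimum of 1 read, 3824 genes were 2-fold higher and 780 lower, and 1786 and 122 passed 4-fold. Of the 3824, 1595 had 0 or 1 mutant reads, where the pseudocount weighs more in the shallower library. With a minimum of 200 reads these numbers were 183, 123, 48 and 10, and 2 lists (muscle, yolk protein) lay above and 1 (vitelline membrane) below the random range, as fewer genes were measured. With identical sequences counted once, 42AB had 0.98, 38C 0.57 and flamenco 0.03, and 29 transposon elements were 2-fold higher and 3 lower. The scale of distinct gene sequences alone moved these log2 ratios by -0.88, and the cause of the rest was not tested. In the inner 80% of the clusters, 20A had -0.26 and flamenco 1.09; the cause was not tested. With GC weighting, 9 genes were 4-fold lower, 1 list lay below the random range, 0 transposon elements were 2-fold lower, and 42AB, 38C, 20A and flamenco had 2.47, 2.15, -0.23 and 1.10, since AT-rich heterozygote reads lose weight. With unannotated reads alone, 42AB turned to -1.70 and flamenco had 0.18. For 38C and 80EF there was no value, because 38C had 12 and 0 such reads and 80EF had 0 in both libraries.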

Other observations

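The weighting of genes by GC content was chosen after the data were seen. Reads outside genes and transposons held other differences. Reads annotated to the mitochondrial genome were 3.92-fold lower in the mutant library than in the heterozygote library. No GC-weighted value is given for them. Unannotated reads on the sequence named M, 200 and 179, went the other way, at 3.34 (3.04 to 3.64). Of 12 small structural RNAs past the read minimum, 10 were at least 2-fold lower. These included U2 snRNA (snRNA:U2:14B), at -1.92 (-1.97 to -1.86), U1 snRNA (snRNA:U1:21D), at -1.07, and the U3 snoRNA (snoRNA:U3:54Ab), at -1.84. 7SL RNA, the RNA of the signal recognition particle, was higher, at 0.90 (0.89 to 0.91). Among rRNAs, 18S was 572-fold and 28S 64.4-fold higher relative to gene reads, and reads named rRNA precursor 3.86-fold. Unannotated reads on the sequence named xtas numbered 65 and 24, a log2 ratio of 2.08 (1.32 to 2.76). The RNA roX2, known from dosage compensation in males, had 7 and 18 reads, a log2 ratio of 4.80 (3.53 to 6.36).

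GC content and log2 ratio went together across genes, which are not independent replicates. The median log2 ratio was -0.52 in the tenth of genes with the lowest GC content and 0.24 in the tenth with the highest. After weighting by the trend within genes these medians were -0.27 and 0.05. On chromosome 4, 25 of 52 genes were at least 2-fold lower, and on heterochromatin scaffolds 22 of 33, against 292 of 4754 on the large arms.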
